A study of Mus musculus with 6 samples.

How the data were processed

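Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in natural killer (NK) cells sorted from mouse spleen. The 6 libraries fell into 2 genotypes of 3 libraries each, wildtype and Rroid deficient, and each genotype was assayed with 50000 cells, per the labels. The labels do not say whether the libraries of a genotype came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

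Per the submitters' processing notes, the tools were bcl2fastq 2.16.0, Trimmomatic 0.32, BWA, MACS2 2.1.0, DiffBind, R 3.1.1 and HOMER, and the genome build was mm9. The role and order of these tools, the shift of reads to the transposase cut site and the removal of duplicate or mitochondrial reads were not given in the sources used here. The deposited table held 51775 consensus peaks with a median width of 964 bp, and 1 normalized signal value per peak and library. Per the file headers, each peak carried HOMER's annotation with the nearest gene, the distance to its transcription start site and the genomic class. A nearest gene is an assignment by distance and names no regulated gene.

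The deposited signal values were whole reads divided by 1 factor per library. Within a tolerance of 0.01, 100.0% of the values of each library came out as whole reads, and the factors were proportional to edgeR's TMM effective library sizes computed from those reads. The recovered reads in peaks ranged from 27572006 to 47939665 per library, and the median peak held 151 to 224 reads. Counting error alone is 6.7 to 8.1% at these medians and larger at lower peaks. No peak was listed at 0 in any library, and the lowest value stood for 1 read.

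The columns of the table showed the genotype. Wildtype columns ended in 1, 2 and 3, as the sample titles do, but Rroid-deficient columns ended in 4, 5 and 6, which match no title. Columns were therefore used as replicates without pairing. They are called by the number at the end of the column's name, wildtype libraries 1, 2 and 3 and Rroid-deficient libraries 4, 5 and 6. The design written before the data were examined foresaw either counts or normalized values. Because the deposited unit was a normalized signal, the main test was limma 3.58.1 with an intensity trend on log2 of the value plus a pseudocount of 1. Fold changes are on that scale, which understates changes of low peaks. Benjamini-Hochberg adjustment ran over all peaks, and a peak was called at an adjusted p under 0.05. A planned filter (a value of 10 or more in at least 3 libraries) removed 0 peaks.

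For gene lists, the peaks within 100 kb of the start site of a list's genes were tested with limma's camera against all other peaks, with a preset correlation of 0.01, and adjusted over 16 lists. Camera with an estimated correlation, which also refers its statistic to the few residual degrees of freedom, and limma's fry, which asks whether the peaks of a list move on balance one way, were run beside it. The 16 lists, fixed before the data were examined, covered NK and innate lymphoid cell (ILC) transcription factors, mature NK effector genes, immature NK genes, an E-protein and memory programme, IL-15 and STAT5 signalling, NK receptors, ILC1 and tissue residency, cytokine and chemokine receptors, cell cycle and housekeeping genes. The other lists held markers of T cells, B cells, myeloid cells, dendritic cells, erythroid cells and ILC2 and ILC3. Several genes stood in more than 1 list. The shares of called peaks per genomic class and per chromosome were compared with two-sided Fisher's exact tests, adjusted over 16 and 40 tests. Neighbouring peaks are not independent, so these p-values are too small. The number of genes with 3 or more peaks called in the same direction was set against 10000 seeded random draws of as many peaks.

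Named peaks followed a rule written before the data were examined. It took the 12 largest and 12 smallest log2 fold changes among called peaks whose groups did not overlap and whose mean log2 value lay at or above the median of all peaks, with at most 1 peak per nearest gene. It also took up to 4 called peaks per list with the smallest p, the promoter peaks of up to 2 members without a call, every called peak within 500 kb of the Id2 start site and the Id2 promoter peak, and the 5 genes with the most called peaks in each direction. Peaks named outside this rule are said to be chosen after their values were seen.

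On simulated data for this comparison, 200 of 51775 peaks were changed. The test recovered 37.3% of 1.5-fold, 64.2% of 2-fold and 97% of 4-fold changes, with 7 false calls. In the real data 25.8% of peaks were called, which makes the adjusted limit less strict, so these shares do not carry over. Alternatives were DESeq2 size factors, total reads in peaks, loess normalization by abundance, DESeq2 1.42.0, limma-voom and edgeR 4.0.16 on the recovered reads, pseudocounts of 0.5 and 5, adjusted p limits of 0.01 and 0.1, a log2 fold change of at least 1, the upper part of the peaks by mean value, autosomes only, each library left out in turn, and other definitions of the list peaks. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. GC content, mappability and similarity to sequence elsewhere in the genome were not analysed here.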

Results

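NK cells are cytotoxic innate lymphocytes, and Id2 is a transcriptional repressor that binds E proteins and is required for NK and ILC development. Rroid is a long noncoding RNA locus near Id2. ATAC-seq was used to ask how chromatin accessibility differed between Rroid-deficient and wildtype NK cells of C57BL6 mice, sorted from spleen as CD3- and CD5-negative cells that carried NK1.1 and NKp46. There were 3 libraries per genotype. The wildtype libraries 1, 2 and 3 held 43187774, 47939665 and 39847736 reads in peaks, and the Rroid-deficient libraries 4, 5 and 6 held 27572006, 41167610 and 30762426. Values are normalized reads per peak, given as mean ± SD with n = 3 per genotype unless said otherwise, and coordinates are mm9.

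Libraries of the same genotype resembled each other more than libraries of different genotypes. Across peaks, which are not independent replicates, Pearson's r of log2 values was 0.987 to 0.992 within genotypes and 0.959 to 0.973 between them. The first principal component, with 62.8% of the variance, had all 3 wildtype libraries on one side and all 3 Rroid-deficient libraries on the other. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 3.45 to 9.6 within genotypes, so no library was a copy of another.

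Upstream of Id2, a stretch of peaks differed plainly between the genotypes. A block of 13 adjacent peaks on chromosome 12 (26000744 to 26079794), all annotated as intergenic with Gm17746 as the nearest gene, was almost without reads in the Rroid-deficient libraries. These peaks held 4696, 6666 and 5047 reads in wildtype libraries 1, 2 and 3 and 39, 54 and 47 reads in Rroid-deficient libraries 4, 5 and 6. The summed value was 4904 ± 709.9 in wildtype and 53.4 ± 2.8 in Rroid-deficient cells, 1.09% of wildtype, so all 6 libraries matched their genotype labels at this site. The block began 219.8 kb and ended 298.8 kb from the Id2 start site, on its upstream side. The labels name a knockout of Rroid, so the block may be DNA that is absent rather than chromatin that is closed. Reads in peaks do not tell these apart. The next peak on the Id2 side (25996412 to 25997185) kept 96.9% of its wildtype value, and the next peak on the far side (26099705 to 26100611) kept 68.9%.

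At Id2 itself, outside this block, accessibility fell. The peak 3153 bp downstream of the Id2 start site (25777102 to 25778507, at the end of the gene) fell from 1841 ± 220.2 to 684.1 ± 53.2, a log2 fold change of -1.42 (SE 0.11, adjusted p = 8.94e-08, limma with Benjamini-Hochberg adjustment). The Id2 promoter peak (25780258 to 25781499) fell from 4977 ± 457.8 to 3157 ± 245.0 (log2 fold change -0.66, adjusted p = 3.55e-05), and the peak 3285 bp upstream (25782524 to 25785961) fell from 4379 ± 411.2 to 2923 ± 105.1. Of 26 peaks between Id2 and the block, 17 fell and 0 rose in the limma test. The deepest fall among them was at 25824433 to 25824962, from 116.3 ± 17.6 to 31.9 ± 20.8.

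Within 500 kb of the Id2 start site, 22 of the 49 peaks outside the block fell, 1 rose and 26 did not pass the test. Over these 22 peaks the log2 fold change ranged from -2.0 to -0.46, and the Rroid-deficient value was 27.4 to 73.0% of wildtype. Elsewhere 12% of peaks were called lower, against 44.9% here (Fisher's exact test, two-sided, odds ratio 5.96, p = 1.11e-08). Neighbouring peaks are not independent, so this p-value is too small. Adjusted over the peaks of the window alone, 24 flanking peaks were lower and 3 higher. By distance from the block, 20 of 32 peaks were called lower within 250 kb, 5 of 13 from 250 to 500 kb, 3 of 23 from 500 to 1000 kb and 0 of 11 from 1000 to 2000 kb, but 13 of 52 from 2000 to 5000 kb. The rising peak, in the first part of Rrm2 (25391650 to 25395660, log2 fold change 0.28), lost its call when single libraries were left out (adjusted p = 0.165 without wildtype library 2). The fall of the next peak beyond the block (log2 fold change -0.56) was not called by edgeR or DESeq2 (adjusted p = 0.054 and 0.0638).

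**Figure D1:**
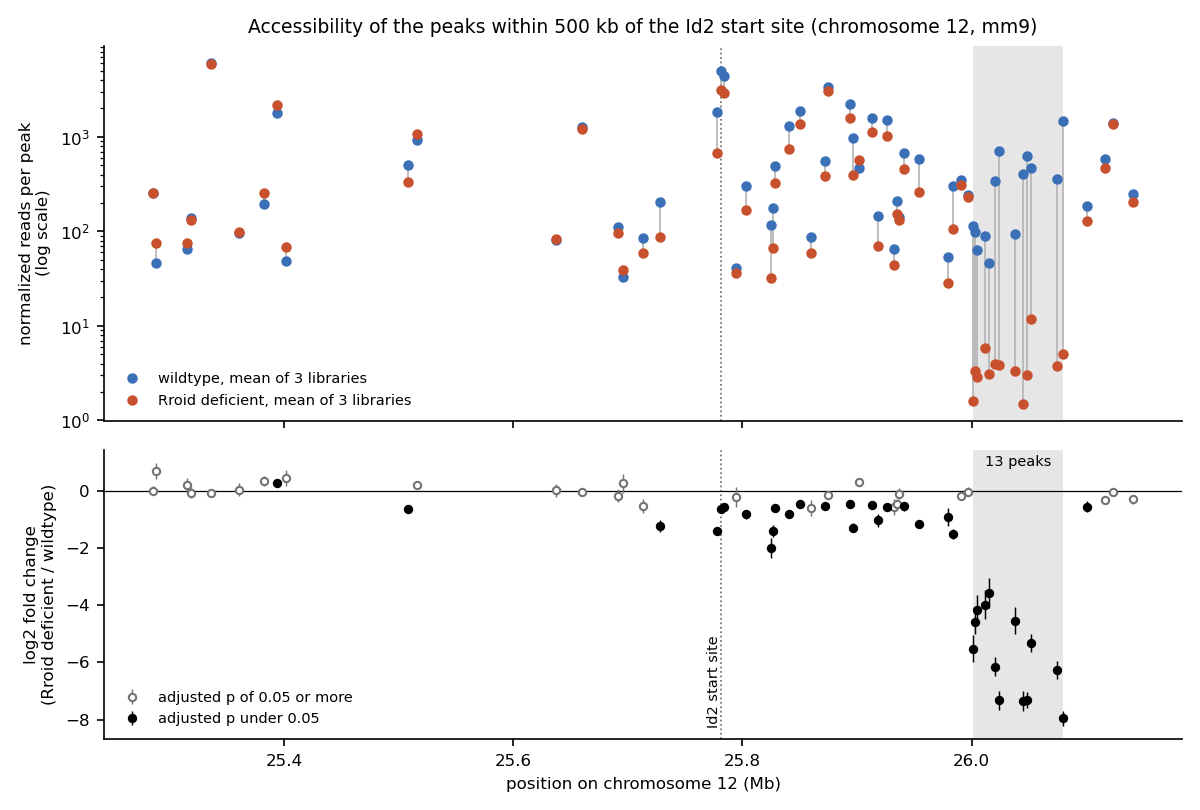
Peaks within 500 kb of the Id2 start site (dotted line) along chromosome 12 in Mb. The upper panel gives mean normalized reads per peak on a log axis for 3 wildtype (blue) and 3 Rroid-deficient (red) libraries, and the lower panel the log2 fold change with its SE, filled where the adjusted p was under 0.05; the 13 peaks in the grey block held 1 to 16 reads per peak in each Rroid-deficient library.

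Across the genome, accessibility differed in both directions, and the balance depended on how high the peaks were. Of 51775 peaks, 7126 rose and 6257 fell (limma, adjusted p under 0.05), 25.8% of all, and the nearest genes numbered 6959. In the lowest decile of peaks by mean value 652 rose and 176 fell, and in the highest decile 168 rose and 815 fell. When only the upper part of the peaks by mean value was tested, 3525 rose and 4771 fell, so the balance turned. Among called peaks, the median log2 fold change was 0.85 for rising peaks, against a fall of 0.59 for falling peaks. At least 2-fold differences were reached by 2641 rising and 991 falling peaks. Rising calls were more often at low peaks, where counting error is larger and a call needs a larger change. Sizes of change were not compared at matched peak height. The groups did not overlap at 96.0% of called peaks and at 40.1% of all peaks, where chance gives 10%. Without wildtype library 2 the count of falling peaks was 4039. In the lowest decile of peaks by mean value, the median log2 deviation from the mean of the libraries was -0.01, -0.16 and -0.03 in wildtype libraries 1, 2 and 3 and 0.31, -0.13 and 0.20 in Rroid-deficient libraries 4, 5 and 6, so the 2 shallowest libraries stood apart there.

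**Figure D2:**
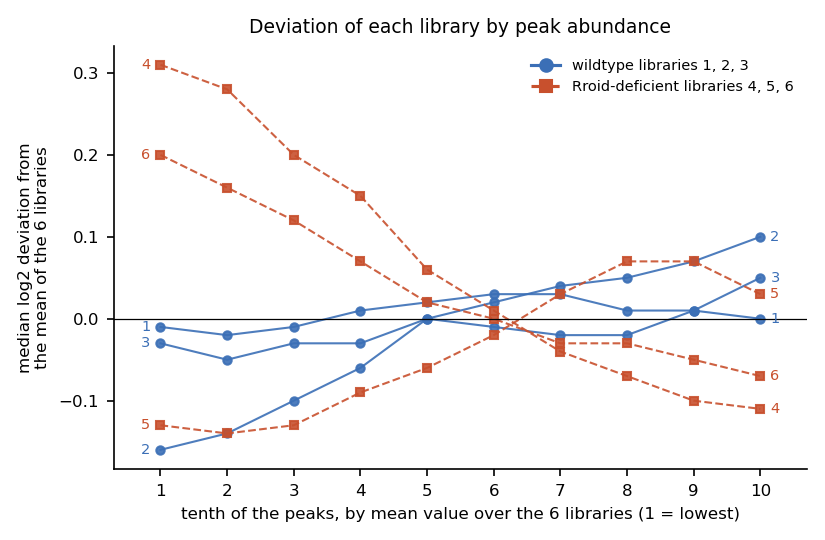
Median log2 deviation of each library from the mean of the 6 libraries, by decile of the peaks from the lowest to the highest mean value, for 3 wildtype (solid blue) and 3 Rroid-deficient (dashed red) libraries. In the lowest decile, Rroid-deficient libraries 4, 5 and 6 stood at 0.31, -0.13 and 0.20.

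Near genes of mature NK effector function, more peaks fell than rose. This list holds cytotoxic granule genes, chemokines, and trafficking and maturation genes. Of its 189 peaks near 25 genes, 78 fell, 8 rose and 103 did not pass the test. There were 16 genes with falling peaks only, 1 with rising peaks only, 6 with both and 2 with neither. At S1pr5, a sphingosine-1-phosphate receptor used in NK cell exit from lymphoid organs, an intronic peak (chromosome 9, 21050704 to 21051306) fell 2.86-fold, from 844.7 ± 169.3 to 292.8 ± 45.1 (adjusted p = 2e-06, limma). At Zeb2, a transcription factor of terminal NK maturation, a peak 1554 bp upstream of the start site (chromosome 2, 44970098 to 44970609) fell 2.86-fold, from 288.3 ± 7.4 to 100.1 ± 4.8. Gzma and Gzmb, which encode granzymes, and Itgam were chosen after their values were seen. Gzma had falling peaks at 7 of 8 sites, the deepest (chromosome 13, 113884339 to 113885019, intron) from 493.9 ± 41.4 to 204.5 ± 17.9, and Gzmb at 4 of 6 sites, Itgam at 3 of 6. Against the direction of the list, a distal peak near Fasl (chromosome 1, 163680687 to 163682049, intergenic) rose 3.24-fold and one near Prf1, which encodes perforin (chromosome 10, 60770957 to 60771743, intergenic), rose 2.50-fold. Among promoter-proximal peaks without a call, Klf2 held 8935 ± 253.0 and 8295 ± 370.0 normalized reads in wildtype and Rroid-deficient cells, and Itgax 783.3 ± 159.5 and 692.9 ± 56.3.

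The median log2 fold change of the mature list was -0.29, and camera placed it below other peaks (adjusted p = 7.43e-08 with the preset correlation). This call was lost with an estimated correlation (adjusted p = 0.766), and fry gave an adjusted p of 0.0435. Adjusted over the list alone, 86 peaks were lower and 11 higher.

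Near genes of immature NK cells and of the E-protein and memory programme, more peaks rose than fell. Of 145 peaks near 18 genes of the immature list, 59 rose, 10 fell and 76 did not pass the test. Of 177 peaks near 23 genes of the E-protein list, 67 rose, 9 fell and 101 did not pass, and 14 of its 24 genes also stood in other lists. Kit, a receptor tyrosine kinase of progenitor cells, gained a peak near its start site (chromosome 5, 75970584 to 75972350, intron) from 600.2 ± 22.6 to 1909 ± 164.1, 3.17-fold (log2 fold change 1.67, SE 0.10, adjusted p = 9.06e-09, limma). Tcf7, which encodes the transcription factor TCF-1, rose 2.34-fold at an intronic peak (chromosome 11, 52087316 to 52090627), from 1247 ± 266.2 to 2890 ± 273.0. Id3, another E-protein inhibitor of the Id family, rose at all 7 of its peaks within 100 kb, and 3.20-fold at the peak 453 bp from its start site (chromosome 4, 135699391 to 135700989, intron), from 441.2 ± 79.5 to 1408 ± 173.3. Cxcr5, a chemokine receptor, also rose at all 7 peaks, with its promoter (chromosome 9, 44334198 to 44335150) going from 46.3 ± 10.1 to 261.2 ± 31.2. Emb and Gpr183 rose 1.85-fold and 1.86-fold at their peaks with the smallest p. The Cd27 promoter peak (chromosome 6, 125186461 to 125189627), chosen after its values were seen, rose from 1143 ± 47.8 to 1961 ± 102.2. Some members had falling peaks only: Lef1, which stood in both lists, had 5 falling and 0 rising peaks, Xcl1 of the immature list 3 and 0, and Tcf3 of the E-protein list, chosen after its values were seen, 1 and 0. Promoter peaks of Bcl2 (3541 ± 48.9 and 3239 ± 54.0 in wildtype and Rroid-deficient cells) and Socs1 (6966 ± 149.2 and 6905 ± 542.7) had no call.

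The median log2 fold change was 0.27 for the immature list and 0.23 for the E-protein list, and camera placed both above other peaks (adjusted p = 5.58e-07 and 3.69e-07 with the preset correlation). With estimated correlations of 0.047 and 0.062 both had an adjusted p = 0.469, and fry gave 0.00369 and 0.00872. Adjusted over the list alone, 60 peaks were higher and 10 lower in the immature list, and 68 and 9 in the E-protein list. With libraries 4 and 6 left out, a choice made after the data were seen, both lists kept their direction. Over the other alternatives the adjusted p by camera ran from 6.47e-08 to 0.469 and from 4.76e-09 to 0.469. With the preset correlation, splits of the libraries that mixed the genotypes also called 1 to 7 lists, so a camera call alone is weak support.

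**Figure D3:**
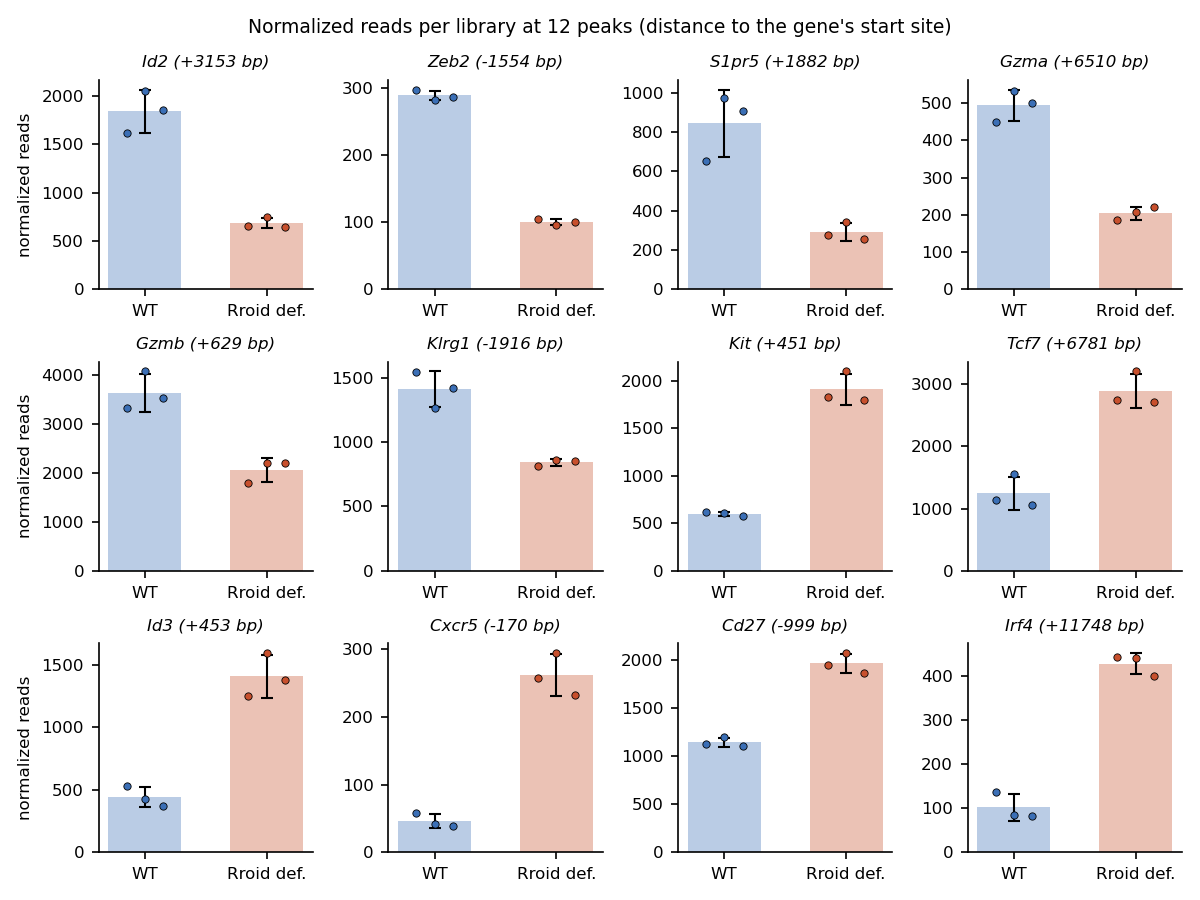
Normalized reads per library at 12 peaks, titled by nearest gene and distance to its start site, for wildtype (WT) and Rroid-deficient cells; bars are means, error bars SD, points the 3 libraries. Gzma, Gzmb and Cd27 were chosen after their values were seen; at Kit the wildtype mean was 600.2 and the Rroid-deficient mean 1909.

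Near NK receptor genes, more peaks fell than rose. Of 145 peaks near 31 genes, 53 fell, 9 rose and 83 did not pass the test, with a median log2 fold change of -0.26. The adjusted p by camera was 1.47e-06 with the preset correlation and 0.678 with the estimated correlation of 0.112. The adjusted p by fry was 0.0169. Adjusted over the list alone, 59 were lower and 10 higher, and the camera call was lost when only promoter peaks were used (adjusted p = 0.0529). Klrg1, an inhibitory receptor of mature NK cells, fell 1.67-fold at a peak 1916 bp upstream of its start site (chromosome 6, 122234166 to 122235368), from 1409 ± 138.3 to 841.8 ± 27.6. Klrb1c and the Klrc genes were chosen after their values were seen. All 9 peaks of Klrb1c, which encodes NK1.1, fell, and so did 8 of 9 peaks of Klra8, one of the Ly49 receptors. The Klra, Klrb1 and Klrc genes are families of closely related copies, so reads could have been split between members and values of single members are uncertain. Klrc1, Klrc2 and Klrc3 went the other way, with 1, 2 and 2 rising peaks and 0 falling ones each. Peaks near the start sites of Ncr1, which encodes NKp46, and Klrk1 had no call, with 1938 ± 102.8 and 1640 ± 246.5 normalized reads at Ncr1 in wildtype and Rroid-deficient cells and 2048 ± 222.9 and 2378 ± 234.0 at Klrk1.

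Transcription factor genes went both ways. Of 295 peaks near 26 genes, 72 fell and 47 rose, and camera did not call the list (adjusted p = 0.133). It was called lower with promoter peaks only (adjusted p = 0.037), with values summed per gene (0.00948), without wildtype library 3 (0.0235) and without Rroid-deficient library 5 (0.0238), in a range of 0.00948 to 0.773 over all alternatives. Irf4 rose at 8 of 12 peaks, 4.27-fold at an intronic one (chromosome 13, 30852082 to 30853668), from 102.2 ± 31.0 to 428.1 ± 24.3. Runx1 had 6 rising and 10 falling peaks, with a 2.27-fold rise at an intronic one (chromosome 16, 92743838 to 92744669). Tbx21, which encodes T-bet, had 4 falling peaks of 11, Eomes 1 of 5 and Zbtb16 9 of 16, each with 0 rising peaks; these 3 genes were chosen after their values were seen. The start-site peak of Gata3 held 5744 ± 284.3 and 5670 ± 61.4 normalized reads in wildtype and Rroid-deficient cells, without a call.

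Genes of cytokine signalling also went both ways. IL-15 and STAT5 signalling had 37 rising and 13 falling peaks of 160 (adjusted p = 0.0799, camera), with a 2.73-fold rise at an Il2ra intron (chromosome 2, 11572970 to 11573628) and a 2.72-fold fall at a distal peak of Il15 (chromosome 8, 85018426 to 85019705, intergenic). The IL-15 list was called higher when scaled to total reads (adjusted p = 0.0499), after loess (0.0172), without wildtype library 2 (0.0144) and without Rroid-deficient library 4 (0.00875), in a range of 0.0015 to 0.926. Cytokine and chemokine receptors had 46 rising and 32 falling peaks of 181 (adjusted p = 0.177). Among them, a peak near Tgfbr1 (chromosome 4, 47322917 to 47324206, intron) rose 3.97-fold and 1 near Il6st (chromosome 13, 113297759 to 113298483, intergenic) rose 3.63-fold. Il12rb2 and Il18rap, chosen after their values were seen, had 5 falling peaks each. ILC1 and tissue residency genes had 14 rising and 16 falling peaks of 103 (adjusted p = 0.809), Cd69 rising 1.79-fold at its start site and Rgs1 falling 1.68-fold at a distal peak. Cell cycle genes had 6 and 4 of 57 (adjusted p = 0.808) and housekeeping genes 5 and 9 of 67 (adjusted p = 0.494). The housekeeping list was called lower with promoter peaks only (adjusted p = 0.037, range over alternatives 0.037 to 0.964).

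Marker genes of other cell types did not move as lists by camera. T-cell markers had 18 rising and 11 falling peaks of 85, with a median log2 fold change of -0.02 (0.04 when scaled to total reads) and a positive mean of 0.12 (camera adjusted p = 0.69, fry adjusted p = 0.0435). The Cd3g promoter (chromosome 9, 44788196 to 44789753) rose from 58.7 ± 5.8 to 352.8 ± 33.5, while the peak at Cd3d (chromosome 9, 44793233 to 44795572), chosen after its values were seen, was 3904 ± 564.2 and 3115 ± 436.2 and fell (log2 fold change -0.33). B-cell markers had 4 rising and 3 falling peaks of 24 and a median of 0.27 (adjusted p = 0.533), with a 3.93-fold rise at the Pou2af1 promoter. Myeloid markers had 5 and 2 of 26 (adjusted p = 0.757, fry adjusted p = 0.0169) and dendritic-cell markers 3 and 6 of 33 (adjusted p = 0.808). Erythroid markers had 1 and 2 of 13 (adjusted p = 0.828), and ILC2 and ILC3 markers 7 and 9 of 45 (adjusted p = 0.757), with a camera direction below other peaks and a median of 0.01 (-0.02 after loess). Adjusted over the list alone, the rising and falling peaks numbered 50 and 84 for transcription factors, 41 and 15 for IL-15 signalling, 52 and 39 for cytokine receptors, 15 and 16 for ILC1 genes, 5 and 2 for cell cycle, and 2 and 5 for housekeeping. Adjusted over the list alone they numbered 18 and 12 for T-cell, 5 and 3 for B-cell, 5 and 2 for myeloid, 3 and 6 for dendritic-cell, 1 and 2 for erythroid and 8 and 10 for ILC2 and ILC3 markers. With an estimated correlation, none of the 16 lists passed.

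**Figure D4:**
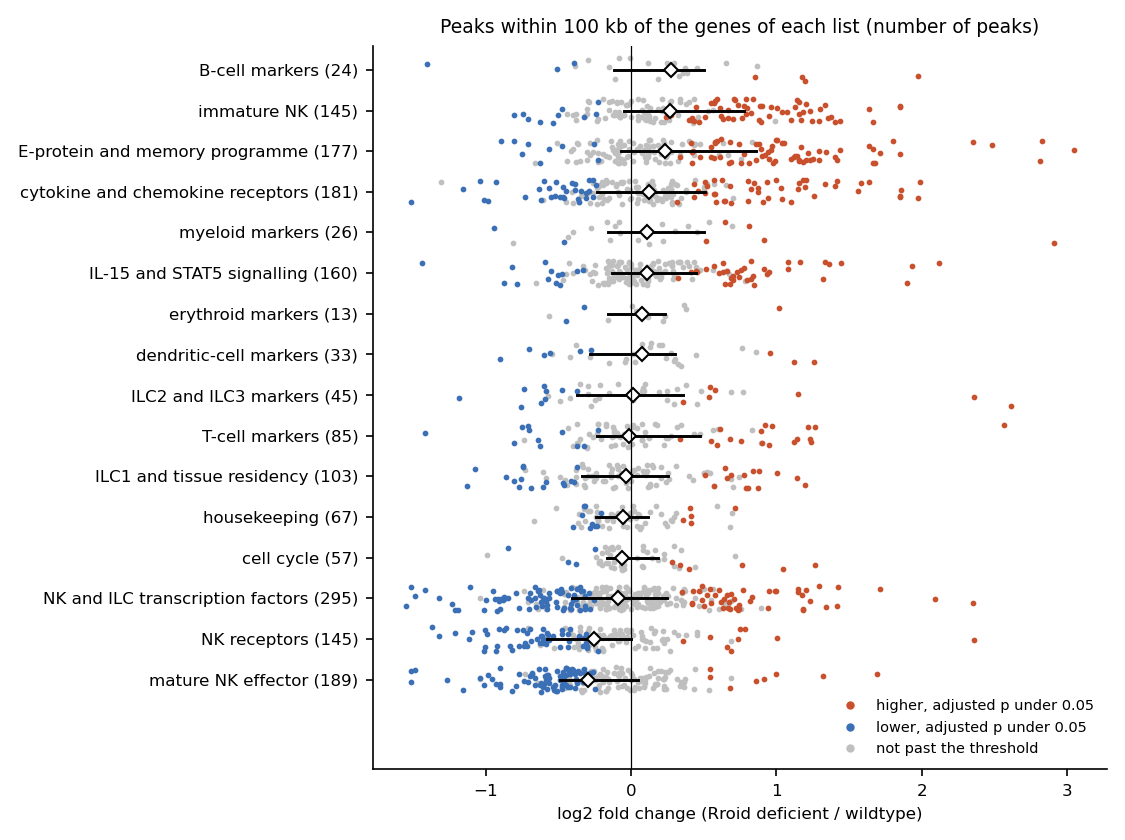
Log2 fold change (Rroid deficient over wildtype) of every peak within 100 kb of the genes of each list, with the number of peaks in brackets; diamonds are medians, black bars the span from the lower to the upper quartile, and colours the call of each peak (red higher, blue lower). Medians ran from -0.29 in the mature NK effector list to 0.27 in the immature NK and B-cell marker lists.

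Among called peaks with a mean log2 value at or above the median, with at most 1 peak per nearest gene, the largest differences lay mostly at distal peaks near genes outside the lists. The largest rise was at an intergenic peak 25523 bp upstream of Col19a1 (chromosome 1, 24619166 to 24620433). Wildtype libraries 1, 2 and 3 had 42.7, 1088 and 139.7 normalized reads there and the Rroid-deficient libraries 17359, 17681 and 18146, while 4 of the other Col19a1 peaks fell. The wildtype libraries differed widely at this peak. Its similarity to sequence elsewhere in the genome was not checked, so its value is uncertain and may not reflect accessibility. Next under these limits were peaks near Spats1 (chromosome 17, 45625173 to 45626357, intergenic), from 129.7 ± 13.1 to 1076 ± 127.3 or 8.23-fold (adjusted p = 3.83e-10, limma), and near Mir7058, Pnrc1, Fam43a, Aox2, Vipr1, Sema7a, Cenpv, Kbtbd11, Rftn1 and Ren2, with rises of 5.99-fold to 7.90-fold. The Ren2 peak was not called by edgeR (adjusted p = 0.0887). Under the same limits, which leave out the block near Id2 and other peaks with few reads in Rroid-deficient cells, the largest falls were near Atp2b4 (chromosome 1, 135659336 to 135660414, intergenic), from 846.4 ± 289.9 to 54.1 ± 17.6 or 15.3-fold (adjusted p = 1.91e-08, limma), Ccdc121 (9.89-fold) and Tspan11 (8.40-fold). The others were near Khdc1c, Nav1, Khdc1b, Ror1, Cftr, Podxl, Loxl2, Khdc1a and Xkr5, with falls of 5.10-fold to 6.59-fold. The Khdc1 genes are neighbouring copies of each other, so values of single members are uncertain.

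Differences clustered along the genome. There were 627 genes with 3 or more rising peaks and 615 with 3 or more falling peaks, against 374.0 ± 14.2 and 287.5 ± 13 (SD) over 10000 random draws of as many peaks (permutation test, p = 0.0001 for each, the smallest the draws can give). Of 4301 pairs of neighbouring called peaks no more than 50 kb apart, 87.5% went the same way, where independent peaks would give 50.2%. Mgst2 had the most rising peaks, 20 of 23, followed by Kbtbd11 with 12 of 12, and then Itgb3, Sik1 and Foxo1 with 11 rising and 0 falling peaks each; Ets1 and Foxp1 also had 11 rising peaks, with 3 and 4 falling ones. Gm17746, upstream of Id2, had the most falling peaks, 30 of 41, with the 13 peaks of the block among them. Mef2c followed with 16 of 28, Pik3r1 with 14 of 39 and Sel1l with 14 of 27. Chl1 and Mir6388 had 13 falling and 0 rising peaks, and Atp10a 13 and 2.

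Promoter peaks were called less often than distal peaks, in a comparison not matched for peak height. Promoter peaks made up 9.1% of rising and 9.1% of falling peaks, against 13.1% and 13% of the other peaks (Fisher's exact test, two-sided, odds ratios 0.66 and 0.67, adjusted p = 7.54e-22 and 2.18e-18). Intergenic peaks were more frequent among both (odds ratios 1.08 and 1.24), and exons were less frequent among falling peaks (0.53). Exons were more frequent among rising peaks (1.16, adjusted p = 0.0312), but with a log2 fold change of at least 1 the direction turned and the call was lost (0.88, adjusted p = 0.309). The share of rising peaks differed from the rest on 8 chromosomes and that of falling peaks on 10. Chromosome 6 had the highest share of falling peaks, 17.8% against 11.7% of the rest (odds ratio 1.63, adjusted p = 3.66e-19). Without peaks nearest to Klr and Clec2 genes, a choice made after the result was seen, it was 16.5%. On the X chromosome 6.9% of peaks rose, against 13.9% of the rest (odds ratio 0.45, adjusted p = 3.22e-14). Its share of falling peaks did not differ from the rest (10.4% against 12.1%, adjusted p = 0.113).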

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

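The edgeR test, the fit without Rroid-deficient libraries 4 and 6 and the random gene lists were chosen after the data were seen; the other alternatives were fixed before the data were examined. No peak was called in opposite directions by the main test and any alternative. Rising and falling peaks numbered 7009 and 6167 by DESeq2, 7026 and 6161 by limma-voom, 7026 and 6324 by edgeR, and 8229 and 4944 when scaled to total reads, which moved the median log2 fold change of all peaks from -0.008 to 0.051. They numbered 3728 and 3652 without libraries 4 and 6, where the lone Rroid-deficient library was taken to vary like the others, 4365 and 3265 at an adjusted p under 0.01, and 2641 and 991 with a log2 fold change of at least 1. The last 2 pairs of counts follow from stricter limits. Why fewer peaks were called without libraries 4 and 6 was not tested. Fewer libraries did not always lower the counts, since 7214 rose and 6304 fell without Rroid-deficient library 5. In the upper part of the peaks by mean value 3525 rose and 4771 fell, so falling peaks outnumbered rising ones there; the cause was not tested. Leaving out 1 library at a time gave 5218 to 7508 rising and 4039 to 6304 falling peaks, the fewest falling without wildtype library 2. Around Id2, outside the block, 8 falling peaks had a log2 fold change of at least 1, and leaving out 1 library at a time left 19 to 22 falling. The 1 rising peak there, Rrm2, became 3 with total reads, 2 with loess, 3 at an adjusted p under 0.1, and 0 at an adjusted p under 0.01, with a log2 fold change of at least 1 or without libraries 4 and 6 (limma, where 28 peaks around Id2 outside the block had an unadjusted p under 0.05 in the full data). Leaving out 1 library at a time gave 0 to 2, and the cause was not tested. Camera called 2 lists higher and 2 lower. With the correlation estimated per list it called 0 higher and 0 lower. The estimated correlations were 0.21 for the mature, 0.112 for the NK receptor, 0.062 for the E-protein and 0.047 for the immature list, against the preset 0.01. Estimating the correlation also changes the degrees of freedom of the test, and the share of each in the lost calls was not tested. At an unadjusted p under 0.05 the estimated correlation left the immature list (p = 0.0407). Without libraries 4 and 6 camera called 4 lists higher, adding IL-15 signalling (adjusted p = 0.0015, range 0.0015 to 0.926) and cytokine receptors (0.0151, range 0.0151 to 0.845); the cause was not tested. Leaving out 1 library at a time gave 2 to 3 lists in each direction. A permutation test with 10000 random gene lists matched on peaks per gene gave p = 0.0001, the smallest they can give, for the same 4 lists (adjusted p = 0.0004). The draws took genes as the unit and left the libraries as they were. They ignore correlation among the genes of a list and so add no independent support. With a log2 fold change of at least 1, 5 chromosomes for rising and 3 for falling peaks stood apart, and 151 and 71 genes had 3 or more peaks, because fewer peaks were counted. Of 2422 comparisons over 144 named peaks, 2351 stayed on their side of the threshold, 61 lost the call, 10 gained one and 0 changed direction. No paired analysis was possible because the numbers of the Rroid-deficient columns match no sample title. The replicate block was therefore not run, and leaving out the low-value filter changes nothing since it removes 0 peaks. With 3 libraries per genotype, the test recovered 37.3% of simulated 1.5-fold changes when 200 of 51775 peaks were changed. In the data 25.8% of peaks were called, which makes the adjusted limit less strict, so that share does not carry over. Peaks without a call may still include missed changes.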

Other observations

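The tests of T cells, of how far the missing block reaches, of background in single libraries and of other splits of the libraries were chosen after the results were seen; those of abundance, B cells, clustering and sequencing depth were written before their results were seen. The features of the next paragraph were chosen after their values were seen.

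On chromosome 3, the region from Mgst2 to Foxo1 (51440335 to 52303968) had 34 rising and 0 falling peaks of 63. A peak near Hist1h4n (chromosome 13, 21903365 to 21905095) went from 992.9 ± 189.9 to 1.2 ± 0.2 normalized reads. A peak near Mir129-1 (chromosome 6, 28877973 to 28879963) went from 893.5 ± 135.2 to 13.8 ± 6.5. Histone genes are a repeated family, so the first value is uncertain. As at the block near Id2, reads in peaks do not tell absent DNA from closed chromatin at either peak. Whether the genotypes differed in genome sequence outside the Rroid locus was not tested. Of 23 peaks that kept under 10% of the wildtype value, 13 lay in the block near Id2. In the Speer gene cluster on chromosome 5 (14914388 to 15211661), 30 of 30 peaks rose, with sums of 1209, 1132 and 1960 in wildtype libraries 1, 2 and 3 and 10319, 3115 and 8450 in Rroid-deficient libraries 4, 5 and 6; these genes are a multicopy family, so values of single members are uncertain. On the X chromosome, 2 peaks in Xist fell (100672691 to 100673382, log2 fold change -0.59, and 100676459 to 100679515, -0.32), as did start-site peaks of Kdm6a (-0.27) and Kdm5c (-0.25). Over all X peaks, 10.4% fell, against 12.1% of the rest (Fisher's exact test, two-sided, adjusted p = 0.113). Whether the animals of the genotypes differed in sex was not tested.

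In Rroid-deficient cells 78 of 189 mature NK effector peaks fell and 8 rose, while 59 of 145 immature NK and 67 of 177 E-protein peaks rose and 10 and 9 fell. The list calls are lost with an estimated correlation (adjusted p = 0.766, 0.469 and 0.469), and an abundance trend is argued against as the whole cause of the gap, since loess normalization left a gap of 0.49 between the list medians, against 0.56 without it. T cells stay open, since the median log2 fold change of 24 T-cell marker peaks (11 genes in no other list) was 0.12, with 95% bootstrap bounds of -0.04 to 0.34 that include the 0.27 of the immature list, and so do B cells (24 peaks of 10 genes, 0.17 after loess, bounds -0.25 to 0.33, against 0.26), although the sort took CD3- and CD5-negative cells with NK1.1 and NKp46. In 7 of the 10 splits of the 6 libraries camera called as many lists, the real one included (real 4, highest other 7), and 10 splits are too few for a share under 0.05; with the preset correlation, splits that mixed the genotypes also called 1 to 7 lists. A shift in the share of mature NK cells, or in Id2 activity within cells, may also underlie the pattern and was not tested.

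Beyond the 13 peaks nearly without reads, 22 of 49 peaks around Id2 fell, 1 rose and 26 did not pass the test. A continuous loss from the block over the 21 falling peaks on the Id2 side is argued against, since the first peak outside the block there kept 96.9% of its wildtype value (95% bounds of its log2 fold change -0.37 to 0.31, against -0.46 at the least lowered flanking peak); for the 1 falling peak on the far side, which kept 68.9% (-0.98 to -0.14), this stays open. Few windows of 49 consecutive peaks elsewhere held as many falling peaks, 274 of 50705, with 32 in the highest. These windows were matched on the number of peaks and not on their length. Clustering of falling peaks in general therefore stays open. Of the 10 splits of the libraries, 1, the real one, called as many peaks in the flanks (real 23, highest other 0 by limma, with at most 3 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. A regulatory effect of the Rroid locus on Id2 is a candidate explanation, which no measurement here tests.

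Low peaks tended to rise and high peaks to fall in Rroid-deficient cells, with a median log2 fold change of 0.19 in the lowest decile and -0.10 in the highest. The mean deviation of libraries 4 and 6, the shallowest, in the lowest decile was 0.26. It was also 0.26 after every library was thinned to the reads of the shallowest, and thinning moved the libraries by 0.01 at most. This argues against the number of reads alone as the source of the deviation. Thinning leaves the make-up of each library as it was, so other differences of the shallow libraries stay open. Background in single libraries stays open too: Rroid-deficient library 5 (-0.13) lay under the highest wildtype library (-0.01), a difference of -0.12, while libraries 4 and 6 lay above all wildtype libraries, but these are the values that showed the pattern. For the count of peaks that differ between the genotypes, 1 of the 10 splits, the real one, called as many (real 13383, highest other 0 by limma, with at most 2983 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05.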
